A study of Malus hupehensis with 9 samples.

How the data were processed

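Phloem of 3 apple rootstocks at bud break was profiled in 9 libraries, 3 of each rootstock. Per the labels' protocols, total RNA was extracted with the mirVana kit, polyadenylated RNA was used, and libraries were made with the TruSeq Stranded mRNA kit. Trimmomatic, a read trimmer, is named in the submitters' processing notes without a version. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Where 2 genes are near-identical copies or overlap, that counting may have split their reads, so single genes carry this uncertainty. A hybrid or a wild species aligned to another genome can also lose reads where its sequence differs.

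The deposited file holds FPKM, reads or fragments per kilobase of gene length, scaled to the library total, for 39951 gene identifiers in 9 columns, all of which were used. The unit comes from the name of the deposited file. The sample of each column was taken from its name, matched to the sample's description or title. The file gives neither names nor descriptions of genes, and no reference was used here. The gene lists planned before the data were examined, among them gibberellin, auxin, cold and phloem genes, were therefore not tested. In their place the rule fixed beforehand for that case was used: the 2 called genes with the largest rise and the 2 with the largest fall in each comparison. Genes outside that rule are named only in the chromosome 10 region, which was also fixed beforehand.

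A gene's FPKM values were whole multiples of a step that depends on its length and on the library. From these steps the library totals, the gene lengths and the whole reads were computed. Whether a unit is a read or a read pair is not known; "read" is used for both. Of 37548 genes above 0 in at least 1 library, 37548 came out whole in every library, within 0.0001 reads plus the rounding of the file, and 2403 genes were at 0 everywhere. The recovered reads summed to 99.920 to 99.955% of the totals found from the steps. The median length was 1398 bases, and 45.3% of lengths were divisible by 3. On 20000 simulated genes the method found 9 of 9 totals and every read of 97.51% of genes, or 99.35% of genes with at least 10 reads in a library. It assumes that the ratio of totals lies between 0.75 and 1.4; that bound was set after earlier versions failed on simulated data, and the simulation covers only such totals. Library totals were 15684510 to 18022986 reads. Counting intervals and floors, the latter taken as 3 reads, cover counting error only, since reads from PCR are not independent molecules.

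Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. A gene was tested if its FPKM was at least 1 in at least 3 of the 9 libraries, which left 26510. Group means of all 9 libraries were fitted together, so that the 3 rootstocks shared 1 estimate of the spread, with empirical Bayes moderation and an intensity trend. The contrast of each pair of rootstocks and a moderated F test among the rootstocks were made. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each contrast. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated data with the real means and spreads of 26510 genes, with 50 genes changed by each fold size, the A1d against WT contrast recovered 12, 66, 84 and 78% of genes changed 2, 4, 8 and 16-fold, with 5 false calls. QZ1 against WT recovered 4, 54, 80 and 78%, with 2 false calls. Each simulated gene had the same spread in all libraries, so the contrasts differed only by the random draw.

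Shared calls were set beside independent lists and 20 simulations of unchanged groups. In these all libraries were drawn at random, with the same spread for every library of a gene, and both contrasts shared the simulated WT. Regions were read from the identifiers, whose form is that of the GDDH13 apple annotation, where the first 2 digits give the chromosome and the last digits the order along it; the file itself does not state this. Other statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

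The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, only the 6 libraries compared, no intensity trend, a test against a 1.5-fold change, the replicate number as a block, and leaving out each library in turn. Weights per library, voom on the recovered reads, leaving out both A1d replicate 1 and WT replicate 1, and the settings of the genes expressed in some rootstocks only were added after. No pair of libraries held the same values, and every library was used in the main test.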

Results

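Messenger RNA of phloem, the bark tissue that conducts sugars, was measured at bud break in 3 apple rootstocks. WT was Malus hupehensis, an Asian crab apple grown as a rootstock. A1d was a mutant of it that responds only in part to gibberellin, a growth hormone of plants. QZ1 was a columnar hybrid with M. hupehensis as its mother and a columnar apple line as its father; columnar trees grow upright with short side branches. Each rootstock had 3 replicates, and the labels do not say whether these were separate trees, so p-values measure the spread between these libraries, which may be technical. The deposited values were FPKM of 39951 gene identifiers, whose steps gave back whole reads. Library totals were 15684510, 17824890 and 18022986 reads in A1d, 17853477, 17970988 and 17970248 in QZ1, and 16860711, 16615625 and 16775368 in WT. The file does not pair identifiers with gene names, so genes are given by identifier and no pathway is described.

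Most libraries held a similar set of genes, and A1d replicate 1 did not. That library listed 18107 genes at 0, against 7183 to 9029 in the other 8. Among its detected genes, 2.48% had 1 to 5 reads, against 9.98 to 11.71% elsewhere. Its Pearson r with A1d replicates 2 and 3, across 26510 genes on the log2(FPKM + 1) scale, was 0.791 and 0.785, whereas those replicates reached 0.957 with each other. Within QZ1, r was 0.936 to 0.956. In WT, replicates 2 and 3 reached 0.957, and WT replicate 1 had 0.914 and 0.909 with them and 0.915 with A1d replicate 2. Genes are not independent replicates, so these r carry no test.

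**Figure D1:**
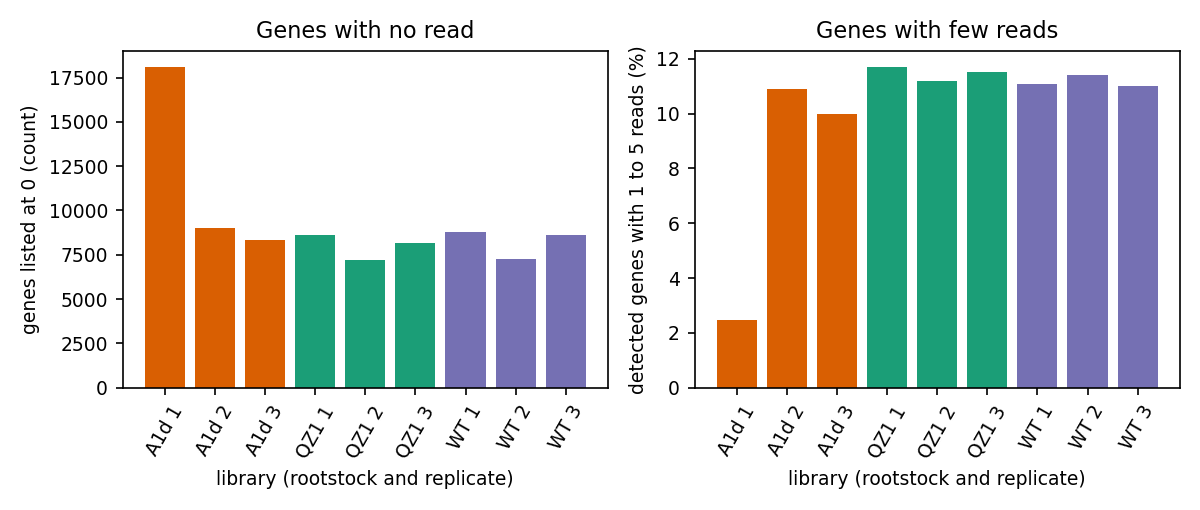
Bars give, for each of the 9 libraries, the number of genes listed at 0 (left) and the percentage of detected genes with 1 to 5 reads (right), coloured by rootstock. A1d replicate 1 stands apart with 18107 genes at 0 and 2.48% of detected genes at 1 to 5 reads.

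The first principal component, with 39.3% of the variance, separated A1d replicate 1, at a score of -194.1, from the rest. The second, with 30.2%, ordered the rootstocks. WT had scores of 41.7, 89.7 and 88.9, A1d 3.1, 5.4 and -9.4, and QZ1 -68.1, -71.2 and -80.0. The rootstocks did not overlap on it. Among all 3 rootstocks, 2608 of the 26510 genes tested (9.8%) differed by limma's moderated F test at a Benjamini-Hochberg adjusted p under 0.05. That count was 5627 without A1d replicate 1, 757, 1089 and 658 without QZ1 replicate 1, 2 and 3, and 926 and 951 without WT replicate 2 and 3.

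**Figure D2:**
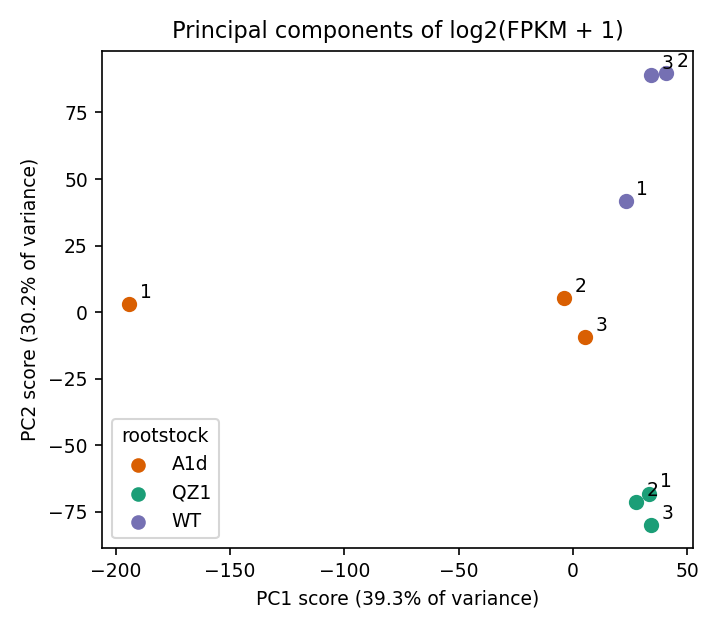
Each point is 1 of the 9 libraries, numbered by replicate and coloured by rootstock, placed by its scores on the first and second principal components of log2(FPKM + 1), which hold 39.3% and 30.2% of the variance. A1d replicate 1 lies at -194.1 on the first, and the second runs from QZ1 through A1d to WT.

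The comparison of A1d with WT asks what differs in phloem between the partly gibberellin-insensitive mutant and its wild type. In A1d 372 genes were higher and 442 lower, 814 in all or 3.07% of those tested, with a median absolute log2 fold change of 1.88. The largest rise was that of MD02G1101900, from 0.0925 ± 0.0395 FPKM in WT to 81.2 ± 85.9 in A1d (SD, n = 3 each). Its log2 fold change was 5.70 ± 0.73 (SE; limma adjusted p = 0.00473, and 0.00034 to 0.16 over the alternatives), and 4.87 without A1d replicate 1. MD11G1104800 had 1 read in the 3 WT libraries together and 3138 in A1d, a ratio of 3060 after scaling by library totals (95% counting interval 549 to 121000). It had 50 ± 38.3 FPKM in A1d and 39.4 ± 4.11 in QZ1. Its log2 fold change of A1d against WT was 5.39 ± 0.44 (SE; limma adjusted p = 0.000651), and 4.82 without A1d replicate 1.

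MD05G1144000 fell most, from 129 ± 98.5 FPKM in WT to 0.368 ± 0.476 in A1d (log2 fold change -5.97 ± 0.92, SE; limma adjusted p = 0.0112, and 0.000876 to 0.249 over the alternatives). The log2 fold change was -7.14 without WT replicate 1 and -5.35 without WT replicate 2. It lost its call without WT replicate 2 (adjusted p = 0.0737) or WT replicate 3 (0.0706), with only the 6 libraries compared (0.0541), and with limma voom on the recovered reads (0.249), which also ended that of MD02G1101900 (0.16). MD02G1092100 fell from 171 ± 33.3 to 4.23 ± 2.19 FPKM (log2 fold change -5.10 ± 0.28, SE; limma adjusted p = 0.000296, at most 0.0163 over the alternatives). QZ1 kept 83.1 ± 5.54 FPKM of this gene, 4.09 log2 units above A1d (limma adjusted p = 0.000457).

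Across all tested genes the median log2 fold change was -0.162 in A1d against WT. It ran from -0.36 in the quartile of shortest genes (84 to 1007 bases) to 0.04 in the longest, and from -0.07 to -0.08 without A1d replicate 1. Quantile normalization moved the median to 0.029 and the calls to 571 higher and 344 lower. A pseudocount of 0.1 also turned the lean, with 293 higher and 248 lower, as did a minimum of 5 FPKM, with 248 and 197. Some settings leaned further to lower genes. There were 314 higher and 563 lower without WT replicate 1, 228 and 391 without A1d replicate 3, 1686 and 2830 with library weights, and 283 and 456 with no filter. Without WT replicate 1 the total of 877 was near the 814 of the main test. Only 456 of those 814 genes kept their call there. Without A1d replicate 1, 1276 genes were called, 666 higher and 610 lower, of which 703 were also called with it, in the same direction. The count was 417 without A1d replicate 2, 426, 493 and 416 without QZ1 replicate 1, 2 and 3, and 160 and 164 without WT replicate 2 and 3, where 105 and 111 of the calls were higher. With only the 6 libraries compared it was 207.

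**Figure D3:**
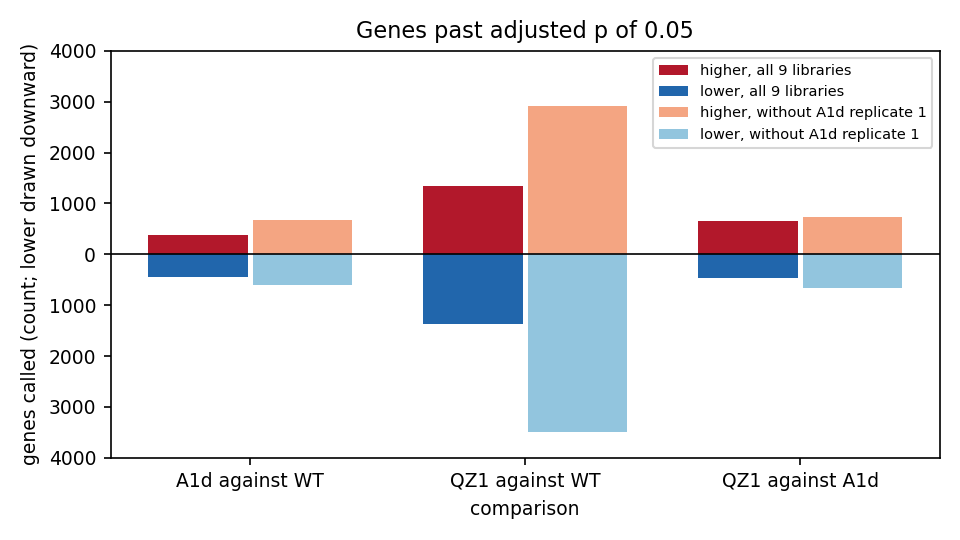
Bars give the number of genes called higher (upward) and lower (downward) in each comparison at an adjusted p under 0.05, with all 9 libraries (dark) and without A1d replicate 1 (light). QZ1 against WT has 1338 higher and 1375 lower genes with all libraries, and 2910 and 3491 without A1d replicate 1.

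The comparison of QZ1 with WT sets the columnar hybrid against its maternal species. It gave the most calls of the 3 comparisons under the main test, with 1338 genes higher and 1375 lower in QZ1, 2713 in all or 10.23%. This balance moved with the setting: there were 4276 higher and 6402 lower with library weights, 3552 and 5344 without both A1d replicate 1 and WT replicate 1, 1205 and 1721 without WT replicate 1, and 486 and 713 without QZ1 replicate 2. It leaned the other way without WT replicate 2 (537 and 372) or 3 (514 and 365) and under quantile normalization (1855 and 1517). MD06G1081500 had no read in any WT library and 80.9 ± 17.4 FPKM in QZ1 (SD, n = 3). That is at least 1210-fold higher, taking 3 reads over the WT group as the floor (limma adjusted p = 0.0201, and 6.23e-05 to 0.0781 over the alternatives). In A1d this gene averaged 21.8 ± 37.8 FPKM, all of it in replicate 3. MD12G1187100 rose from 0.703 ± 1.15 to 272 ± 356 FPKM, a log2 fold change of 6.01 ± 1.34 (SE; limma adjusted p = 0.0236, and 0.00682 to 0.378 over the alternatives). That change was 7.65 without QZ1 replicate 1 and 4.60 without QZ1 replicate 2.

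MD12G1038300 fell from 179 ± 118 FPKM in WT to 2.05 ± 1.74 in QZ1, a log2 fold change of -5.74 ± 0.73 (SE; limma adjusted p = 0.00224, at most 0.0541 over the alternatives). This gene was also low in A1d, at 3.71 ± 1.62 FPKM (limma adjusted p = 0.00943 against WT). MD09G1118100 fell from 61.9 ± 43.7 to 0.166 ± 0.191 FPKM, a log2 fold change of -5.42 ± 0.69 (SE; limma adjusted p = 0.00226, at most 0.0671 over the alternatives), and had 11.6 ± 7.11 FPKM in A1d. The log2 fold change of MD12G1038300 was -5.13 without QZ1 replicate 2 and -6.56 without WT replicate 1, and that of MD09G1118100 -6.18 without WT replicate 3. Voom on the recovered reads ended the calls of both genes.

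The standard error of MD06G1081500 for QZ1 against WT came mostly from A1d replicate 3, through the shared estimate of the spread. It was 1.35 with all libraries and 0.27 without A1d replicate 3 (limma adjusted p = 0.000213). With only the libraries of QZ1 and WT it was 0.20 (limma adjusted p = 6.23e-05). With A1d replicate 3 kept, MD06G1081500 lost its call without QZ1 replicate 1 (adjusted p = 0.0775), 2 (0.0732) or 3 (0.0748) and without WT replicate 2 (0.0781) or 3 (0.0747). MD12G1187100 lost it without QZ1 replicate 2 (0.0652) or 3 (0.0975), without WT replicate 1 (0.0567), 2 (0.0634) or 3 (0.0929), under a test against a 1.5-fold change (0.0582), and with voom (0.378). Without A1d replicate 1 the comparison called 6401 genes, 2910 higher and 3491 lower, 2712 of them shared with the 2713; the median standard error fell from 0.345 to 0.239. Fitting only the 6 libraries of QZ1 and WT called 5559. The count was 795, 1199 and 710 without QZ1 replicate 1, 2 and 3, and 909 and 879 without WT replicate 2 and 3. Without WT replicate 1 it was 2926, and 2000 of the 2713 main calls were kept.

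Genes in the region of chromosome 10 fixed beforehand as the surroundings of the columnar locus, from MD10G1180000 to MD10G1190000, held few of the calls. The chromosome was read from the identifiers, which have the form of the GDDH13 apple annotation. Of 65 genes in the file, 37 were expressed enough to be tested. For QZ1 against WT 1 was called, MD10G1181800, lower in QZ1 (limma adjusted p = 0.0397), and for QZ1 against A1d 1, MD10G1183500, higher in QZ1 (limma adjusted p = 0.0422). For A1d against WT 0 were called by limma and 0 by voom, 2 (5.4%, against 17% of all tested genes) with library weights, and 4 had an unadjusted p under 0.05. Voom called another gene for QZ1 against WT, MD10G1189300, and 0 for QZ1 against A1d, so both limma calls were lost. With library weights, 15 of the 37 (40.5%) were called for QZ1 against WT, where 40.3% of all tested genes were, and 9 (24.3%) for QZ1 against A1d, against 15.8% of all. No difference of the limma share from the rest was detected by Fisher's exact test, with 2.7% called for QZ1 against WT (2-sided p = 0.174; 0.63 for A1d against WT and 1.0 for QZ1 against A1d).

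QZ1 and A1d were also compared directly. In QZ1 662 genes were higher and 474 lower than in A1d, 1136 in all or 4.29%. The excess of higher genes depended on the setting. Quantile normalization gave 605 higher and 599 lower, a pseudocount of 0.1 369 and 364, library weights 2096 and 2091, and a minimum of 5 FPKM 301 and 330. The excess stayed with rescaling to TPM (589 and 467), median-of-ratios scaling (732 and 472) and no filter (727 and 373). MD00G1155400 rose from 1.15 ± 1.99 FPKM in A1d to 71.1 ± 18.3 in QZ1 (SD, n = 3 each; log2 fold change 5.42 ± 0.57, SE; limma adjusted p = 0.0017, at most 0.0285 over the alternatives), and the change was 6.14 without A1d replicate 3. WT had 0.389 ± 0.516 FPKM of this gene. MD12G1187100, which averaged 1.35 ± 2.33 FPKM in A1d, had the largest rise, a log2 fold change of 5.81 ± 1.34 (SE; limma adjusted p = 0.0458, and 0.0254 to 0.372 over the alternatives), and lost its call in 16 of 22 alternatives. That change was 6.58 without A1d replicate 3, 7.44 without QZ1 replicate 1 and 4.40 without QZ1 replicate 2.

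MD13G1124300 and MD03G1218400 were the largest falls in QZ1, and both stood out in A1d. MD13G1124300 had 91.1 ± 54.8 FPKM in A1d, 0.479 ± 0.527 in QZ1 and 1.34 ± 0.951 in WT (log2 fold change of QZ1 against A1d -5.86 ± 0.47, SE; limma adjusted p = 0.000487, at most 0.0271 over the alternatives). MD03G1218400 had 40.2 ± 18.1 FPKM in A1d and 0.220 ± 0.0357 in WT. It had 1 read in the 3 QZ1 libraries against 3450 in A1d, a ratio of 3600 (95% counting interval 646 to 142000; limma adjusted p = 0.000457, at most 0.0123 over the 18 alternatives that tested it).

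Without A1d replicate 3, 1108 genes were higher and 457 lower in QZ1 than in A1d, and without A1d replicate 1, 734 and 658. The count of 1136 became 482 without A1d replicate 2, 155, 347 and 135 without QZ1 replicate 1, 2 and 3, and 682 and 695 without WT replicate 2 and 3. With only the 6 libraries compared it was 432. Without QZ1 replicates 1, 2 and 3 the higher genes were 74, 115 and 60 of those calls.

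Calls against WT overlapped between A1d and QZ1. In both rootstocks 215 genes were higher than in WT and 296 lower, 511 in all or 62.8% of the A1d calls, and 2 were called in opposite directions. Independent lists of these sizes would share 18.8 higher and 22.9 lower genes. At an unadjusted limma p under 0.05, 2522 genes changed in the same direction in both. The mean was 304 in 20 simulations of unchanged groups, where both contrasts shared a simulated WT. Those groups held no changes, and the real WT libraries were not part of them. Unrelated changes in many genes would also exceed 304, so this gap does not measure sharing by itself. The covariance of the log2 fold changes was 0.391, against 0.094 simulated, a difference of 0.297, and their correlation across genes was 0.55, against 0.50. Of the signs 68.3% were the same, against 66.7% simulated, and 73.4% were without A1d replicate 1. Each simulated gene had the same spread in every library. With a shared WT, that setting alone fixes the simulated 0.50 and 66.7%, whatever the data. The real spreads were unequal, with a library weight of 0.08 for A1d replicate 1. These gaps, and that of the covariance, therefore do not measure sharing by themselves.

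Both comparisons used the same 3 WT libraries, too few to split, so part of the overlap may come from them. A1d replicate 3 had reads in 49 of 60 QZ1 genes absent from A1d replicate 2. Part of the overlap may thus come from that library too, and how much was not tested. The shared calls were 947 without A1d replicate 1, 502 higher and 445 lower. These 947 were 74.2% of the A1d calls, beside 16 opposite calls and a correlation of 0.65. Without A1d replicate 2 and 3 the shared calls were 314 and 374. Without QZ1 replicate 1, 2 and 3 they were 224, 285 and 222, and without WT replicate 1, 2 and 3 604, 99 and 97. They were 162 when each comparison was fitted on its own 6 libraries.

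**Figure D4:**
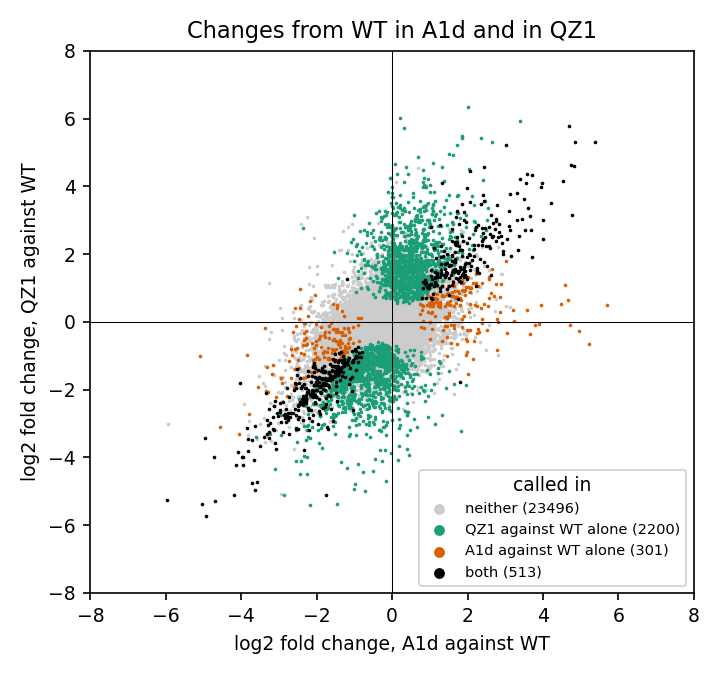
Each point is 1 of 26510 genes, placed by its log2 fold change of A1d against WT and of QZ1 against WT on the log2(FPKM + 1) scale and coloured by where it was called. Of the 513 genes called in both comparisons, 511 lie in the quadrants where the signs are the same.

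Some genes were expressed in all 3 libraries of 1 or 2 rootstocks (FPKM of at least 1) and had no read in any library of the others; this count was chosen after the data were examined. There were 113 such genes. QZ1 alone expressed 40, WT alone 27 and A1d alone 1, while 23 were shared by A1d and QZ1, 15 by A1d and WT and 7 by QZ1 and WT. QZ1 was thus the odd one out in 55, WT in 50 and A1d in 8. WT was the odd one out more often than A1d (2-sided exact binomial p = 1.57e-08, which treats genes as independent), but not more often than QZ1 (2-sided exact binomial p = 0.696; QZ1 was so more often than WT without A1d replicate 3, p = 7.48e-12, and without QZ1 replicate 1, p = 0.0227). The genes of WT alone had a median of 5.02 FPKM, those of QZ1 alone 3.51 and those shared by A1d and QZ1 5.45.

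Without A1d replicate 1 the odd one out was QZ1 in 68, WT in 64 and A1d in 14 genes. Without A1d replicate 3 it was QZ1 in 161, WT in 60 and A1d in 33, since 145 genes were then found in QZ1 alone, and without QZ1 replicate 1 it was QZ1 in 79 and WT in 52. Without A1d replicate 3 the exact binomial p of WT against A1d was 0.0067. With a minimum of 5 FPKM the numbers were 9, 10 and 0.

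**Figure D5:**
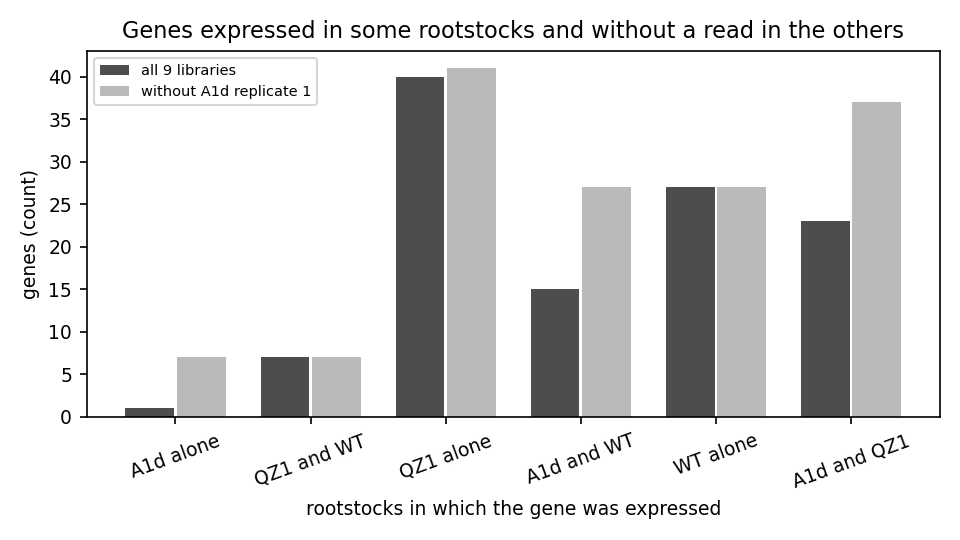
Bars give the number of genes with an FPKM of at least 1 in every library of the rootstocks named and no read in the others, with all 9 libraries (dark) and without A1d replicate 1 (light). QZ1 alone has 40 genes, WT alone 27 and A1d alone 1 with all libraries.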

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

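Library weights, voom on recovered reads, leaving out A1d replicate 1 together with WT replicate 1, and all settings for genes found in some rootstocks only were chosen after the data were examined. In the 66 combinations of an alternative and a comparison, 0 genes of the main calls were called in the opposite direction, but the number of calls moved widely. Below, counts are given for A1d against WT, QZ1 against WT, QZ1 against A1d, the F test and the calls shared against WT, in that order, where they moved by over 1.5 times. A minimum of 5 FPKM gave 445, 1786, 631, 1622 and 287, where fewer genes were tested. Library weights gave 4516, 10678, 4187, 11159 and 3244, with a weight of 0.08 for A1d replicate 1 and 0.38 for WT replicate 1. Voom gave 368, 1734, 598, 1635 and 240. Leaving out both doubted libraries gave 3689, 8896, 2483, 8794 and 2771. The test against a 1.5-fold change gave 216, 727 and 303 for the comparisons and 143 shared, a stricter question by construction. With only the 6 libraries compared the comparisons gave 207, 5559 and 432, with 162 shared. There each fold change stays the same by design, with medians of -0.162, -0.098 and 0.068 as in the main test. Those moves therefore came from the estimate of the spread, which the main test shared among all rootstocks. A pseudocount of 0.1 gave 541 for A1d against WT and 733 for QZ1 against A1d. The causes of the other moves were not tested.

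Leaving out each library in turn gave 160 to 1276 calls for A1d against WT, 710 to 6401 for QZ1 against WT, 135 to 1565 for QZ1 against A1d, 658 to 5627 for the F test and 97 to 947 shared. The highest came without A1d replicate 1, except for QZ1 against A1d (without A1d replicate 3). The lowest came without WT replicate 2 for A1d against WT, WT replicate 3 for the shared calls, and QZ1 replicate 3 for the others. Leaving out a library of the rootstock not compared keeps the fold changes of a comparison. The 416 to 493 calls of A1d against WT without a QZ1 library thus moved through the shared spread and the genes tested. So did the 6401 of QZ1 against WT without A1d replicate 1. The 814 calls of A1d against WT therefore relied in part on the QZ1 libraries. A1d was the odd one out in 8 to 33, QZ1 in 59 to 161 and WT in 50 to 65 of the genes found in some rootstocks only. A minimum of 5 FPKM left 0, 9 and 10 of these.

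Replicate numbers did not pair the libraries: same-numbered residuals correlated at -0.18 to 0.04, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block the counts were 420, 1966, 577, 1621 and 295.

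Of 260 log2 fold changes of named genes under the alternatives, 225 kept their call, 35 lost it and 0 changed sign; 19 were lost when 1 library was left out. MD03G1218400 had no value without any 1 of the A1d libraries, because it then failed the filter. The planned tests of gene lists, and counts of their members, were not run, because the file has no gene descriptions. Simulated 2-fold changes were recovered for 12% of genes in A1d against WT and 4% in QZ1 against WT. Each simulated gene had the same spread in every library, so 12% and 4% differ only by the random draw. They do not compare the 2 contrasts, and the unequal spread of the real libraries was left out. The simulation changed far fewer genes than were called here, so these shares may not hold for the real contrasts. Of the 2713 genes called in QZ1 against WT, 1203 higher and 1231 lower ones changed at least 2-fold on the log2(FPKM + 1) scale. That scale understates the change of low genes, so some of the rest may have changed 2-fold or more in FPKM.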

Other observations

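Of the tests here, those on A1d replicates 1 and 3, and the splits and dropout test of the genes found in some rootstocks only, were chosen after the result was seen; those on chromosomes and neighbours were chosen after the calls were known. Called genes lay side by side in identifier order, counted among expressed genes only, more often than random draws of expressed genes. Of the 1338 genes higher in QZ1 than in WT, 373 (27.9%) were next to another of them, against 130.5 in the mean draw, and of the 1375 lower genes 260 (18.9%), against 138.8. For A1d against WT it was 67 of 372 higher genes, against 10.3, and 66 of 442 lower genes, against 14.6. In each case the permutation p was 0.001, the smallest that 1000 draws can give.

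Calls were unevenly spread over the 17 chromosomes. For A1d against WT the share of tested genes called ran from 1.87% on chromosome 8 to 4.8% on chromosome 11 (permutation p = 0.0001, the smallest that 10000 permutations can give). For QZ1 against WT it ran from 8.03% on chromosome 14 to 12% on chromosome 9 (permutation p = 0.0002), and for QZ1 against A1d from 2.65% to 6.0% on chromosomes 14 and 9 (permutation p = 0.0001, the smallest). Genes are not independent, and neighbours called together make such p-values too small.

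A1d replicate 1 listed 18107 genes at 0. Depth does not account for this: A1d replicates 2 and 3, thinned to its total, listed at most 9179. A WT or QZ1 library under a wrong label is also excluded, since of 146 genes expressed in WT or QZ1 and absent from A1d replicates 2 and 3 it had a read in 3. Few starting molecules copied many times may be the source, as a hypothesis: only 2.48% of its detected genes had 1 to 5 reads, and genes expected at 10 to 40 reads were at 0 in 62.92%. Of its counts of 20 to 99, 75.3% were even (95% Wilson interval 74.1 to 76.5), against 50.3 to 51.8% elsewhere. Few molecules do not by themselves predict even counts. Their source was not tested, and whether a unit is a read or a read pair is not known. No biological explanation was tested.

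A1d replicate 3 and WT replicate 1 each lay toward other rootstocks. Of 60 QZ1 genes absent from A1d replicate 2, A1d replicate 3 had reads in 49, at 29.79% of the QZ1 level (median 25%), and of 24 such WT genes in 13, at 14.73% of the WT level but a median of 1.6%, so that few genes carried it. QZ1 RNA mixed in at 1 share is excluded as the whole cause, because of 28 QZ1 genes absent from the other A1d and all WT libraries 6 had no read where the pooled share of 49.4% predicted at least 22, while 6 stood above 70%; RNA of another plant, or a tree of another genotype, may be involved and was not tested. WT replicate 1 was displaced from the other WT libraries by 49.8% of the way to A1d and 37.0% of the way to QZ1, yet genes absent from those libraries reached only 0.31% of the A1d level (95% Poisson upper bound 0.58) and 0.26% of the QZ1 level (0.96), which excludes mixing of either RNA at such shares. Differences between trees or in harvest stay open for it, untested.

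Among genes found in some rootstocks only, WT was the odd one out in 50 and QZ1 in 55, while A1d, described as a mutant of WT, was in 8; QZ1 and WT did not differ detectably with all libraries (2-sided exact binomial p = 0.696), but QZ1 led 161 to 60 without A1d replicate 3 (p = 7.48e-12) and 79 to 52 without QZ1 replicate 1 (p = 0.0227). Dropout in A1d replicate 1 alone is excluded as the whole cause of the gap between WT and A1d, since without that library the counts were 64 and 14 (2-sided exact binomial p = 8.58e-09). Without A1d replicate 3 WT was so in 60 and A1d in 33 (2-sided exact binomial p = 0.0067), so that library may account for part of the gap and stays open. A1d replicates 1 and 3 were not left out together, so how much of the gap they make jointly was not tested. Stretches of the genome that differ in WT may account for part, as a hypothesis whose prediction was written before its test. Of the 50 genes 4 lay next to another, against 0.2 in random draws (permutation p = 0.005), which leaves 46 unpaired. So did 4 of the 55 genes with QZ1 as the odd one out (permutation p = 0.006). Genes called in QZ1 against A1d, where WT has no part, clustered too: 153 of 662 higher and 71 of 474 lower genes, against 32.6 and 16.7. The clustering is thus not particular to WT, and this test cannot tell such stretches from a general clustering. A different origin of the trees, and sequence variants that cost reads in alignment, stay open and were not tested.

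Other splits were counted for each number of calls and for the 113 genes found in some rootstocks only. For these, 1 of the 280 splits of the 9 libraries into groups of 3, the real one, gave as many, and the next gave 57. That is the smallest share these splits can give, for a count chosen after the data were examined. A random grouping is thus an unlikely source of their total. Which rootstock stands apart is not tested by it, nor is whether libraries group because replicates are technical. For the F test, 1 of 100 splits drawn from 280, the real one, gave as many as 2608 genes, and the highest other gave 1419. This is again the smallest share possible, and a random grouping is an unlikely source of that count. For the pairs of rootstocks, 10 splits of 6 libraries are too few for a share under 0.05. There 1 of 10 splits, the real one, gave as many calls in each comparison: 814, 2713 and 1136, against a highest other of 0 in each.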
